A study of Homo sapiens with 6 samples.

How the data were processed

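RNA was sequenced from HaCaT cells, an immortalised human keratinocyte line, in 6 libraries of 2 groups that carry the titles mod and Nvs, with 3 libraries each. The labels give the cell line as HaCaT and the cell type as keratinocyte, but the source and tissue as skin, and their protocol speaks of both tissue and cells; the samples were treated as cell cultures. The group of each library was taken from its title. Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was enriched by poly(A) selection, strand-specific libraries were made by the dUTP method, and paired ends of 150 bp were read. The labels call the replicates of a group biosamples and do not say that they came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical.

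Gene-level counts were deposited as 1 table with a row per gene symbol, and the sequencing depth below is the total of its columns. FPKM values for the same symbols and libraries were deposited as a second table, normalised by the authors for transcript length and library total. The only genome build in the submitters' processing notes is hg38. The aligner, the counter, the gene annotation, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here. Dividing count by FPKM gave the same transcript length in all 6 libraries within 1 percent for all but 23 of 12579 genes with a total count of at least 200, so both tables rest on the same counts and the FPKM values scale by library total. These transcript lengths and the genomic spans of a RefSeq table of assembly GRCh38 were used to examine gene length. Of the 21961 symbols, 21609 were found in that table, which also gave the gene biotypes. Coordinates printed in the results are those of GENCODE release 29 on GRCh38.

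Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its group rule (minimum count 10, minimum total 15), which left 14617 genes. Libraries were scaled by TMM, and the quasi-likelihood F test compared Nvs with mod in a model with the group as its sole term. P-values were adjusted by the Benjamini-Hochberg method, a gene was called at an adjusted p under 0.05 with no fold threshold, and every fold change is Nvs minus mod on the log2 scale. The standard error was taken as the size of the log2 fold change divided by the square root of F. Levels are TMM-scaled CPM values as returned by edgeR, given as mean ± SD over 3 libraries. TMM sets the typical gene to a change near 0, no spike-in is named in the labels, and a change of total RNA per cell cannot be read from these values. Without TMM, the median gene moved by -0.77 (log2) in Nvs, so every rise or fall is stated relative to the typical gene.

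Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, over lists with at least 3 tested members, with Benjamini-Hochberg adjustment over the 29 lists that qualified of 31. The same test with an estimated correlation was run beside it and called 0 lists at an adjusted p under 0.05 (10 had an unadjusted p under 0.05). That form takes its degrees of freedom from the 6 libraries instead of the genes, so it is less able to call a list. Its p-values rose even where the estimate lay below 0.01. NRF2 targets (estimate -0.0049) went from an unadjusted camera p of 0.000641 to 0.0196, and EGFR ligands (-0.146) from 0.00163 to 0.0320. The loss of calls is therefore not a measure of correlation between genes alone. The lists, fixed before the data were examined, were NRF2 targets, antioxidant enzymes, collagen chains, collagen processing, matrix proteases, protease inhibitors, elastic fibre and hyaluronan, TGF-beta signalling, AP-1 and immediate early genes, EGFR ligands, inflammatory cytokines and NF-kB targets, interferon response, p53 targets, nucleotide excision repair, apoptosis regulators, senescence and secretory factors, cell cycle, keratinocyte differentiation, basal keratinocyte and hemidesmosome, stress keratins and antimicrobial proteins, the unfolded protein and integrated stress response, heat shock proteins, hypoxia and glycolysis, cholesterol biosynthesis, aryl hydrocarbon receptor targets, metallothioneins, autophagy and lysosome, and mitochondrially encoded mRNAs. Markers of fibroblasts, of melanocytes and of leukocytes and endothelium served as lists of other cell types. Genes were named by a rule fixed with the lists. It took the 10 protein-coding genes with the largest fold change in each direction among called genes with a mean CPM of at least 5 and no overlap between groups, 18 genes set in advance for their place in photoaging, and members with the smallest adjusted p of each list. Of the list members, 3 were named for a called list and 2 for any other. These are fewer than the rule allowed, and the cut by call was not part of it. Genes named outside the rule are said to be so.

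The tests were tested on simulated data first. In counts simulated for the Nvs against mod comparison with 200 changed genes among 14284 fitted, the gene test recovered 8% of the genes changed 1.25-fold, 49.0% at 1.5-fold, 82.4% at 2-fold and 96% at 4-fold, with 4 false calls among 122. Far fewer genes were changed there than were called in the data, so these shares need not hold for the data. In a simulation of camera over 14617 genes, 3 of 3 shifted lists and 0 of the others were called. Its genes were drawn independently, so it does not bear on the effect of correlation between genes.

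Alternatives covered DESeq2 1.42.0 (its size factors in edgeR and its own Wald test), scaling by library total, no low-count filter, a stricter one of 1 CPM in 3 libraries, protein-coding genes only, a threshold of log2 1 on the fold change, limma-voom, limma with trend on log2(FPKM + 1) and on log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5, the replicate number as a block, the fry test, an estimated correlation, and each library left out in turn. Fits without mitochondrially encoded genes, fits without genes of uneven replicate counts, and list tests after removal of a loess trend of fold change on gene length were chosen after seeing the data. Genes were called uneven when their highest count reached 100 and the highest CPM was at least 5 times the lowest within a group. There were 162 of them among 11664 genes with a highest count of at least 100. Replicate libraries differed by more than sampling noise in every pair of a group (chi-square per degree of freedom of 11.4 to 15.0), so none was treated as a duplicate.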

Results

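The series compared HaCaT keratinocytes exposed to UVB radiation with such cells that were also treated with vesicles from beet (Beta vulgaris), as its design text states, and its title names photoaging, oxidative stress and collagen synthesis. The labels of the libraries do not match that text in full. The 3 mod libraries are labelled as UV-induced, whereas the 3 Nvs libraries carry a control label and no mention of vesicles. The values were not used to decide between these descriptions, and the groups are called mod and Nvs throughout. Total counts per library ranged from 45637046 to 51369628 in mod and from 41120058 to 44080808 in Nvs.

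Transcripts of the mitochondrial genome took a far larger share of the Nvs libraries. They made up 30.5% ± 0.817 of all counts in mod and 52.6% ± 0.751 in Nvs (SD, n = 3, exact permutation p = 0.1, two-sided, the smallest p that 3 against 3 libraries allow, as for each measure of this paragraph). The 13 mitochondrial mRNAs, which encode subunits of the respiratory chain and of ATP synthase, rose from 19.2% ± 0.554 to 30.4% ± 0.551 of counts, and the mitochondrial ribosomal RNAs from 11.2% ± 0.350 to 22.2% ± 0.390. Ribosomal protein mRNAs went from 5.05% ± 0.155 to 9.82% ± 0.558 of the counts outside the mitochondrial genome. Fewer genes had at least 1 read in Nvs (17109 ± 84.3) than in mod (18839 ± 369), and the counts left for nuclear genes were 20385153 ± 1040738 against 33945527 ± 2354312. The TMM factors were 1.29 to 1.32 in mod and 0.762 to 0.774 in Nvs.

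**Figure D1:**
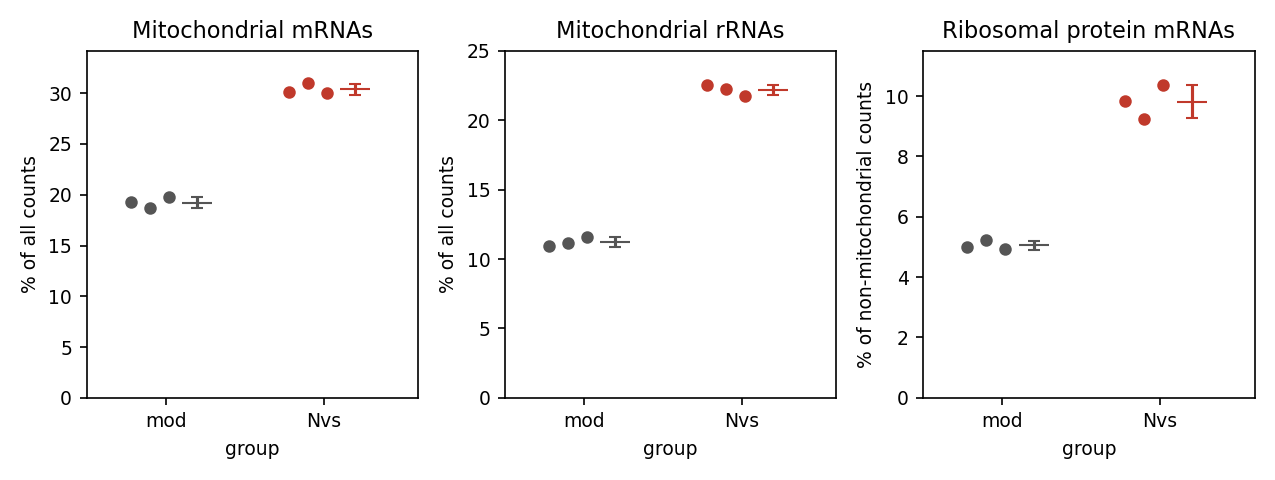
Share of counts in each library (points) with the mean and SD of each group (bars, 3 libraries), as percent of all counts for mitochondrial mRNAs and rRNAs and as percent of non-mitochondrial counts for ribosomal protein mRNAs. All 3 Nvs libraries lie above all 3 mod libraries in each panel.

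Relative to the typical gene, a large part of the transcriptome differed between the groups. The edgeR quasi-likelihood test called 6328 of 14617 genes, 43.3%, of which 3337 were higher in Nvs and 2991 lower, with a median fold of 1.48 among them. In 53.6% of the tested genes the libraries of one group all lay above those of the other, against 10% expected by chance. Scaled by library total instead, the calls split into 589 higher and 9938 lower, and the FPKM values, which share that scaling, gave 577 and 8827. A change of at least 2-fold was found for 814 genes in the rising and 443 in the falling direction. Fold change also followed gene length: the median was 0.56 for protein-coding genes spanning under 3.16 kb and -0.45 in the bin of the longest.

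**Figure D2:**
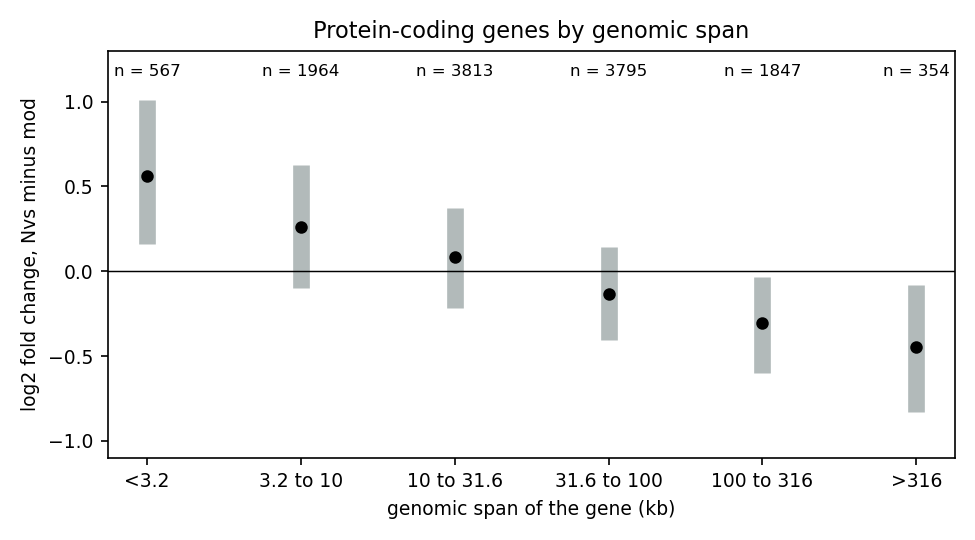
Log2 fold change, Nvs minus mod, of protein-coding genes in 6 bins of genomic span (kb, number of genes above each), with medians as points and the range between quartiles as bars. Medians go from 0.56 in the bin of the shortest genes to -0.45 in that of the longest.

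Among the called protein-coding genes with a mean CPM of at least 5 and no overlap between groups, the largest rises were those of H4C3, a replication-dependent histone H4 gene (0.511 ± 0.0516 to 23.1 ± 4.16 CPM), and SPRR1A, a precursor of the cornified envelope at chromosome 1, 152985231 to 152985500 (2.51 ± 0.342 to 85.0 ± 3.48 CPM, log2 fold change 5.08 ± 0.10 SE, adjusted p = 2.65e-12). CSF2, which encodes the cytokine GM-CSF, rose from 1.01 ± 0.459 to 11.4 ± 0.455 CPM. On the log2 scale TRAF1, an adaptor of TNF receptor signalling, rose by 3.03 ± 0.12, KRT17, a keratin of stressed epidermis, by 2.91 ± 0.06, and IL6 by 2.76 ± 0.27. IFI27, BRD2, FLII and SLC27A3 were also among the 10 largest, but their counts were uneven within groups and they are uncertain. The counts of IFI27 in the Nvs libraries were 178, 180 and 3646, and without the third its log2 fold change dropped from 3.58 to 0.70. Without mod replicate 1, the log2 fold changes of BRD2, FLII and SLC27A3 were 4.38, 4.07 and 4.56 in place of 3.26, 3.16 and 3.07. Without Nvs replicate 3 those of FLII and SLC27A3 were 2.01 and 2.44. The 10 largest falls among such genes were those of SMAD6, an inhibitor of BMP signalling (20.6 ± 0.650 to 5.33 ± 0.402 CPM, log2 fold change -1.95 ± 0.12 SE, adjusted p = 2.23e-08), MX2, an interferon-induced GTPase, the basement membrane collagen genes COL4A1 and COL4A5, and ADAM23, CNTN1, DOCK1, MGAT5, GPR132 and TTLL11, between -1.76 and -1.46. None of these rises and falls was adjusted for the trend with gene length, and most of the falling genes are long.

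Among genes of the oxidative stress response, more rose than fell relative to the typical gene. Of 23 tested NRF2 targets, 14 rose and 3 fell (camera adjusted p = 0.00265, but adjusted p = 0.0947 with an estimated correlation), with a median log2 fold change of 0.28 that turned to -0.48 when libraries were scaled by total count (camera adjusted p = 0.155). Ferritin light chain FTL, an iron store, went from 582 ± 18.6 to 1313 ± 66.1 CPM (1.17 ± 0.05, adjusted p = 2.70e-09), FTH1 rose by 1.06 ± 0.05, AKR1C3, an aldo-keto reductase, rose, and HMOX1, the haem-degrading oxygenase at chromosome 22, 35380361 to 35394214, rose from 9.29 ± 0.673 to 24.5 ± 2.76 CPM (1.40 ± 0.12, adjusted p = 4.96e-07). NQO1, a quinone reductase, rose by 0.37 ± 0.06, which became -0.39 by library total. The 3 members that fell, named after their values were seen like the other exceptions within lists, were ABCC3, a transporter, SLC7A11, the cystine importer, and GCLC, which catalyses the first step of glutathione synthesis. Among 20 antioxidant enzymes, 14 rose and 2 fell (camera adjusted p = 0.00406, adjusted p = 0.346 with an estimated correlation), with a median of 0.39 that was -0.37 by library total (camera adjusted p = 0.185). Removal of the gene length trend took that median from 0.39 ± 0.51 (SD over genes) to 0.26 ± 0.44 with an adjusted p of 0.0190. The glutathione peroxidases GPX2 (1.32 ± 0.06), GPX4 (1.11 ± 0.06) and GPX1 (0.87 ± 0.09) and the peroxiredoxin PRDX5 (0.84 ± 0.06) rose. The superoxide dismutases rose less, SOD2 by 0.56 ± 0.05 and SOD1 by 0.54 ± 0.08, and by library total they turned to -0.20 and -0.22. CAT, catalase, fell (-0.57 ± 0.11, adjusted p = 0.000698), as did GSR, glutathione reductase.

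Collagen genes and the enzymes that process collagen were mostly lower in Nvs. Of 14 tested collagen chains, 8 fell and 2 rose, with a median log2 fold change of -0.80 (camera adjusted p = 0.00353, adjusted p = 0.202 with an estimated correlation). COL4A1, at chromosome 13, 110148963 to 110307233, fell from 20.6 ± 2.02 to 6.34 ± 1.02 CPM (-1.70 ± 0.14, adjusted p = 4.72e-07), COL5A1 by 1.31 ± 0.10, COL4A2 by 0.99 ± 0.07, and COL17A1, the hemidesmosomal collagen, from 1038 ± 11.4 to 703 ± 11.7 CPM (-0.56 ± 0.05, adjusted p = 5.55e-07). The 2 that rose were COL27A1 (0.60 ± 0.06, -0.16 by library total) and COL7A1, the anchoring fibril collagen, which gained 0.30 ± 0.07 but stood at -0.45 by library total. COL1A1, a chain of the main dermal collagen, had 10.8 ± 1.14 CPM in mod and 9.07 ± 0.702 in Nvs (-0.25 ± 0.13, adjusted p = 0.160, not called). By library total COL1A1 was at -1.01, where the median gene was at -0.77. COL3A1 had 1 read in each of 2 mod libraries and 0 elsewhere and was not tested, and COL1A2 was not found in the count table. Of 22 collagen processing genes, 13 fell and 0 rose (14 fell when adjusted over the list alone), with a median of -0.47 (camera adjusted p = 5.64e-05, adjusted p = 0.0902 with an estimated correlation). They included SERPINH1, a collagen chaperone (135 ± 0.838 to 78.7 ± 4.07 CPM, -0.78 ± 0.05), and the prolyl hydroxylases P4HA1 (-0.94 ± 0.09) and P3H2 (-0.68 ± 0.07). Among 18 genes of elastic fibres and hyaluronan, 8 fell and 3 rose (10 and 4 when adjusted over the list alone; camera adjusted p = 0.0410, adjusted p = 0.167 with an estimated correlation). CD44, a hyaluronan receptor, and EFEMP1, a fibulin, fell by 0.61 ± 0.05 and 0.55 ± 0.06. HAS3, a hyaluronan synthase, rose by 0.64 ± 0.05, though it was -0.12 by library total. After removal of the gene length trend, the median of collagen chains went from -0.80 ± 0.70 (SD over 14 genes) to -0.57 ± 0.65 with an adjusted p of 0.0762. That of elastic fibre and hyaluronan genes went from -0.55 ± 0.62 to -0.37 ± 0.53 (18 genes) with 0.111. The latter list had 0.0663 without mod replicate 1, 0.155 by library total and 0.0593 with the stricter count filter.

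The matrix proteases, which degrade collagen, moved in both directions and were not called as a list (6 rose and 5 fell of 18, camera adjusted p = 0.624, adjusted p = 0.656 with an estimated correlation). MMP1, interstitial collagenase, fell from 200 ± 17.6 to 151 ± 5.00 CPM (-0.41 ± 0.06, adjusted p = 0.000179). MMP3 and MMP9 were not called, at 0.87 ± 0.51 and -0.68 ± 0.31, with levels near or below 2 CPM. The urokinase receptor gene PLAUR rose by 1.16 ± 0.07. PLAU, which encodes urokinase, rose by 0.45 ± 0.05, a value that was -0.31 by library total. Of 9 protease inhibitors, 6 fell and 2 rose (6 and 3 when adjusted over the list alone; camera adjusted p = 0.233). TIMP1 fell by 0.36 ± 0.08, while SERPINB3 rose by 1.11 ± 0.09. Of 19 TGF-beta signalling genes 2 rose and 5 fell (camera adjusted p = 0.277), among them INHBA, which encodes an activin subunit (2.44 ± 0.07), and TGFBI (-1.01 ± 0.05).

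**Figure D3:**
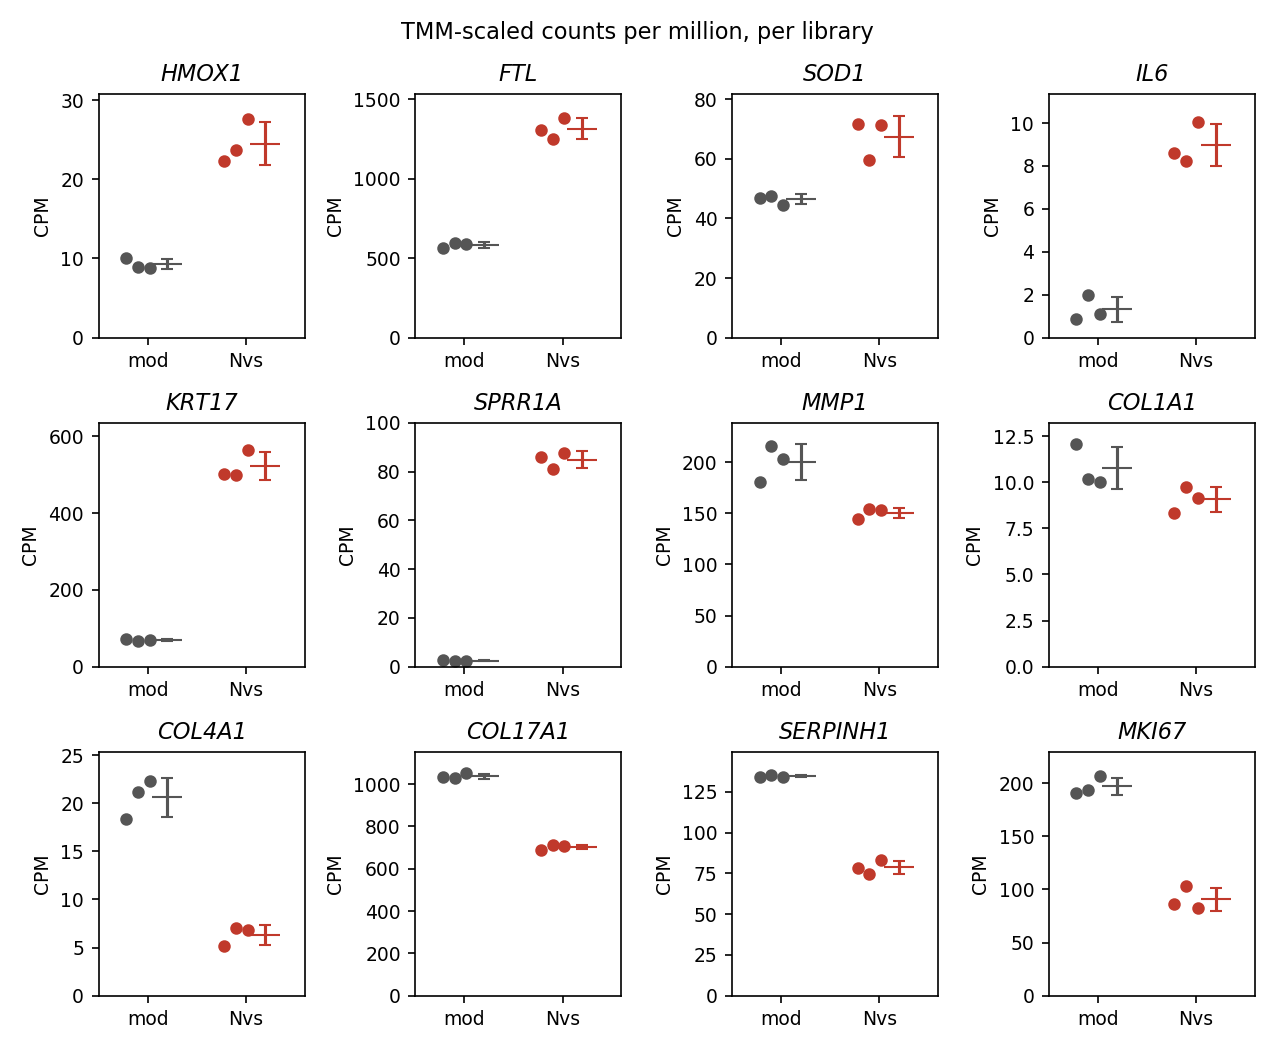
TMM-scaled CPM of 12 genes in each library (points), with mean and SD of the 3 libraries per group (bars); each vertical axis starts at 0. HMOX1, FTL, SOD1, IL6, KRT17 and SPRR1A are higher in Nvs, MMP1, COL4A1, COL17A1, SERPINH1 and MKI67 lower, and COL1A1 was not called; by library total SOD1 turns to -0.22.

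Most tested immediate early, inflammatory and epidermal stress genes rose relative to the typical gene. Of 18 AP-1 and immediate early genes, 14 rose and 0 fell (15 rose when adjusted over the list alone), with a median of 0.95 that stayed positive, at 0.19, by library total (camera adjusted p = 4.24e-08, adjusted p = 0.0902 with an estimated correlation). ATF3, a stress-induced transcription factor, rose from 26.3 ± 0.747 to 125 ± 3.65 CPM, JUND by 1.98 ± 0.06 and FOSL1 by 2.14 ± 0.07. Of 6 tested members of the EGFR ligand list 5 rose, with a list median of 0.67 that became -0.09 by library total (camera adjusted p = 0.00473, adjusted p = 0.131 with an estimated correlation). They included HBEGF (1.14 ± 0.09), AREG (0.88 ± 0.10) and TGFA (0.41 ± 0.07, -0.34 by library total). NRG1 (0.26), also among the 5, binds other receptors of the EGFR family. Among 22 inflammatory cytokines and NF-kB targets, 16 rose and 1, LIF, a cytokine of the IL6 family, fell, with a median of 0.78 that dropped to 0.02 by library total (camera adjusted p = 3.90e-06, adjusted p = 0.0902 with an estimated correlation). CXCL8, a neutrophil chemokine, went from 0.617 ± 0.412 to 5.37 ± 0.258 CPM (3.13 ± 0.38, and 3.80 without mod replicate 3), TNFAIP3, an inhibitor of NF-kB, rose by 1.27 ± 0.07, and NFKB2 rose. Of 13 stress keratins and antimicrobial proteins, 12 rose and 0 fell, with a median of 1.33, and 0.57 by library total (camera adjusted p = 3.24e-06, adjusted p = 0.0947 with an estimated correlation). KRT17 went from 69.4 ± 2.48 to 522 ± 36.5 CPM, KRT16 rose by 1.68 ± 0.06 and S100A9, a calprotectin subunit, went from 13.1 ± 0.407 to 37.1 ± 0.857 CPM.

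Among keratinocyte differentiation markers more genes rose than fell, and among basal markers more fell than rose; the difference between the lists was not tested. Of 20 differentiation genes, 9 rose and 2, the cornified envelope plakins EVPL and PPL, fell (median 0.61, -0.15 by library total; camera adjusted p = 0.00896, adjusted p = 0.131 with an estimated correlation). SPRR1B rose by 2.09 ± 0.05 and FLG, filaggrin, by 2.14 ± 0.11. Of 19 basal and hemidesmosome genes, 11 fell and 3 rose (median -0.23; camera adjusted p = 0.0393, adjusted p = 0.335 with an estimated correlation). The integrin genes ITGA6 and ITGB1 fell by 0.80 ± 0.05 and 0.69 ± 0.06. KRT14, a basal keratin, rose by 0.63 ± 0.06 but was -0.13 by library total. After removal of the length trend, the median of the differentiation list went from 0.61 ± 1.32 (SD over genes) to 0.26 ± 1.22 with an adjusted p of 0.236. That of the basal list went from -0.23 ± 0.37 to -0.12 ± 0.33 with 0.0456. The basal list had 0.0663 without mod replicate 1, 0.0537 without mod replicate 3, 0.0758 without Nvs replicate 1, 0.0586 without Nvs replicate 3 and 0.0727 with the replicate number as a block.

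Cell cycle genes were lower in Nvs, with 18 of 33 falling and 2, the licensing factor CDT1 and thymidylate synthase TYMS, rising, though both were below 0 by library total (19 and 2 when adjusted over the list alone; median -0.36; camera adjusted p = 0.000219, adjusted p = 0.0902 with an estimated correlation). MKI67, the proliferation marker, fell from 197 ± 8.29 to 90.6 ± 11.0 CPM (-1.12 ± 0.08), CENPF by 0.97 ± 0.06 and TPX2 by 0.83 ± 0.06. Of 24 p53 targets, 12 rose and 3 fell (12 and 4 when adjusted over the list alone), with a median of 0.34 that was -0.42 by library total (camera adjusted p = 0.0103, adjusted p = 0.135 with an estimated correlation). BBC3, a pro-apoptotic BH3 gene, went from 8.13 ± 0.728 to 45.9 ± 4.09 CPM (2.50 ± 0.10), CDKN1A, the p21 cell cycle inhibitor, rose by 0.89 ± 0.06 GADD45A by 0.91 ± 0.05, and BTG2 also rose. Of 28 interferon response genes, 12 fell and 5 rose (13 and 5 when adjusted over the list alone; median -0.32; camera adjusted p = 0.0218, adjusted p = 0.198 with an estimated correlation and 0.226 by library total). The 5 include IFI27, whose rise is uncertain, and 2 members of the list had uneven counts, IFI27 among them. OAS3 fell by 0.60 ± 0.05, whereas ISG15 rose by 1.45 ± 0.07 and OASL by 0.81 ± 0.05 (0.69 and 0.05 by library total). Of 8 aryl hydrocarbon receptor targets, 5 rose and 1 fell (median 0.45, -0.31 by library total; camera adjusted p = 0.0172, adjusted p = 0.135 with an estimated correlation and 0.163 by library total). CYP1B1 rose by 1.14 ± 0.08. ALDH3A1 and TIPARP rose by 0.67 ± 0.06 and 0.54 ± 0.05 but stood at -0.09 and -0.22 by library total. The 13 mitochondrial mRNAs all rose, with a median of 1.39 and of 0.63 by library total (camera adjusted p = 5.73e-11, adjusted p = 0.131 with an estimated correlation), among them MT-ND1 (1.66 ± 0.05), MT-ND6 (1.39 ± 0.05) and MT-ND2 (1.45 ± 0.05).

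**Figure D4:**
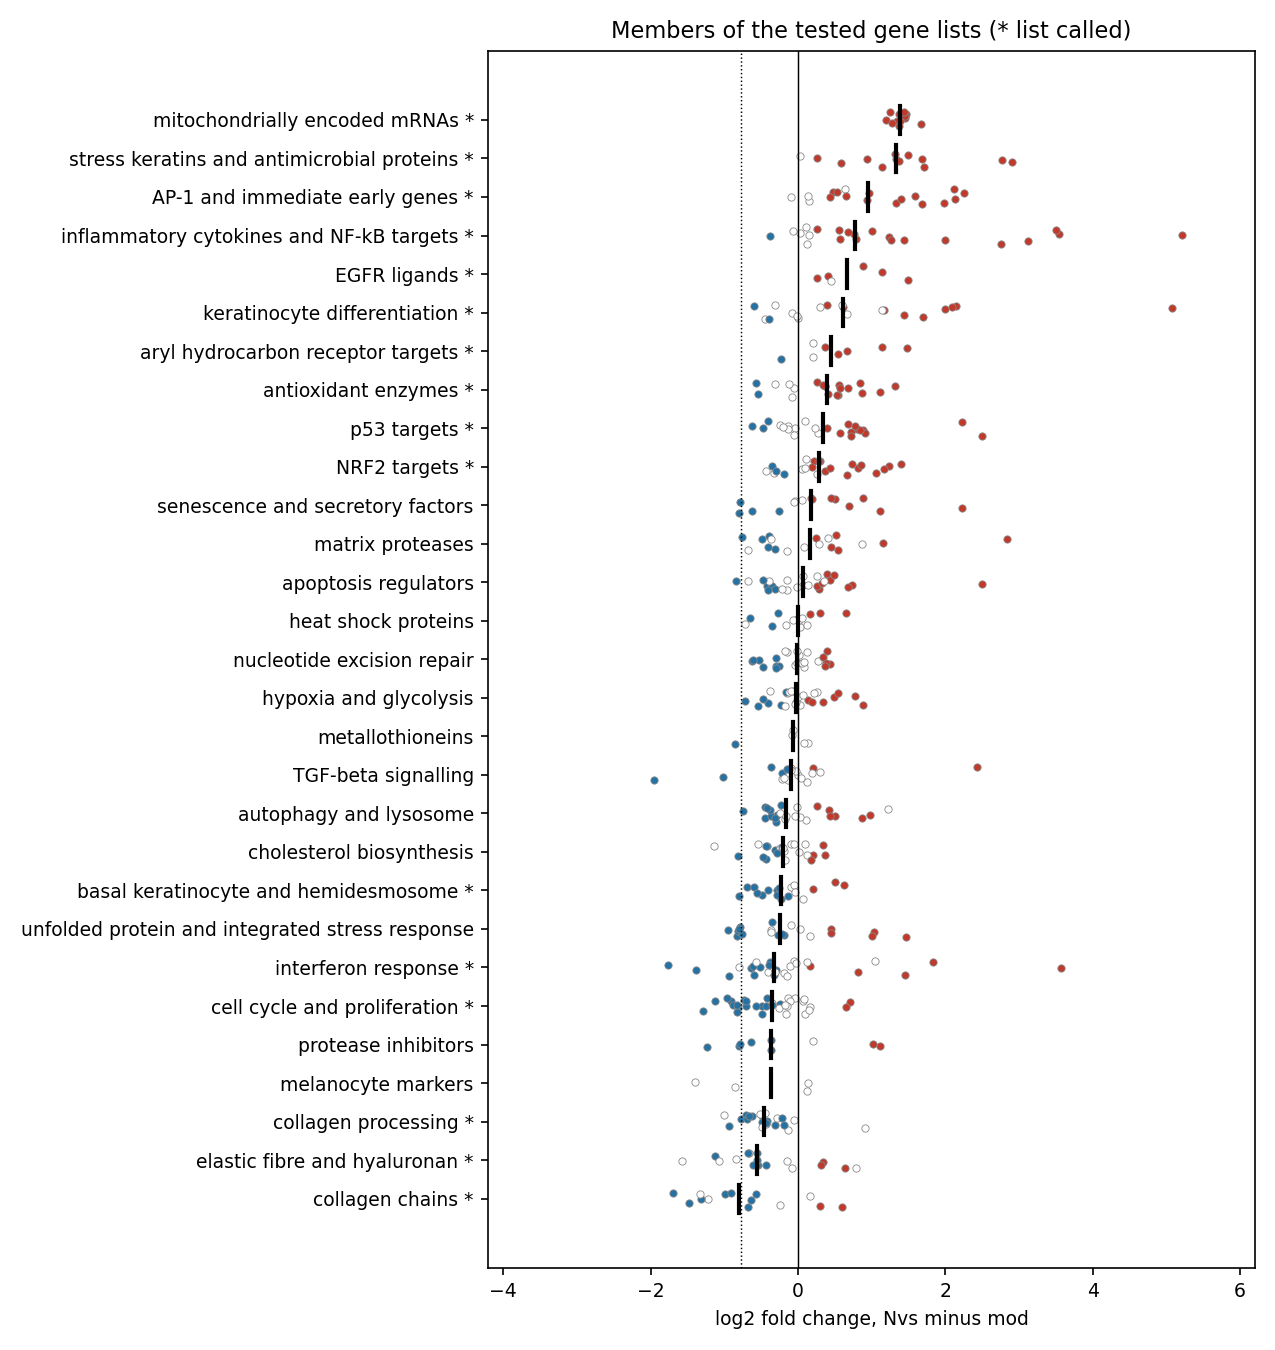
Log2 fold change, Nvs minus mod, of each tested member (points) of the 29 tested gene lists, with list medians as black bars; red and blue points were called higher and lower, open points were not called, and asterisks mark the 16 called lists. The solid line is 0 and the dotted line at -0.77 is the shift of the median gene by library total: adding it moves, of the called lists, the medians of NRF2 targets, antioxidant enzymes, p53 targets, aryl hydrocarbon receptor targets, EGFR ligands and keratinocyte differentiation below 0.

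The other lists were not called by camera with TMM scaling. By library total, camera called 3 of them in the falling direction: nucleotide excision repair (adjusted p = 0.0121), cholesterol biosynthesis (0.0109) and heat shock proteins (0.0450). Their medians by that scaling were -0.77, -0.95 and -0.76, against -0.77 for the median gene. The medians of nucleotide excision repair and heat shock proteins thus did not lie below the typical gene. In the unfolded protein and integrated stress response list 5 rose and 10 fell of 20 (adjusted p = 0.271), with rises of ATF4 (1.01 ± 0.05) and of PPP1R15A (1.47 ± 0.05), both of the integrated stress response. Among the 10 that fell, named after their values were seen, were PDIA4 (-0.95), HSPA5 (-0.83) and HSP90B1 (-0.78). The list test after removal of the length trend called this list lower (adjusted p = 0.0111). Nucleotide excision repair had 5 rising and 8 falling of 24 (adjusted p = 0.624), among the latter POLE and RPA1, and apoptosis regulators 9 and 6 of 26 (9 and 7 when adjusted over the list alone; adjusted p = 0.624), with BIK at 0.74 ± 0.08, or -0.02 by library total. Senescence and secretory factors had 8 and 4 of 15 (adjusted p = 0.354), with CDKN2B at 1.12 ± 0.09. For heat shock proteins the counts were 3 and 3 of 14 (adjusted p = 0.691), with HSPA8 and HSP90AB1 falling. The list's median was 0.00306 and its mean -0.06. Hypoxia and glycolysis genes had 7 and 6 of 26 (7 and 7 when adjusted over the list alone; adjusted p = 0.724; median -0.03, mean 0.01), with PFKFB3 at -0.71 ± 0.06 and ADM at 0.54 ± 0.06, which was -0.22 by library total. Cholesterol biosynthesis had 4 and 8 of 23 (adjusted p = 0.120), with SQLE at -0.41 ± 0.06. Autophagy and lysosome genes had 6 and 10 of 24 (adjusted p = 0.479; median -0.17, mean 0.01), with SQSTM1 at 0.98 ± 0.09 and GABARAPL1 at 0.87 ± 0.05. Of 5 metallothionein list members only the zinc exporter gene SLC30A1 was called, at -0.85 ± 0.11 (adjusted p of the list 0.624), and MT2A was at 0.08 ± 0.07, or -0.68 by library total. For lists without a second count, the numbers adjusted over the list alone were those given.

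Markers of other cell types reached at most 5.91 CPM without TMM in any library. Of 11 fibroblast markers 5 were in the table and 1, PI16, was tested (0.22 ± 0.63, adjusted p = 0.811, and -0.53 by library total). Of the melanocyte markers 4 were tested and 0 called, MLANA and SOX10 included (list adjusted p = 0.624), at up to 3.38 CPM in any library; MLANA, with counts of 10, 0 and 0 in Nvs, was called lower without Nvs replicate 1. Of 13 leukocyte and endothelial markers 2 were tested, CD14, not called, and CD74 (0.77 ± 0.20), which had 169 to 290 counts per library and stood at 0.01 by library total.

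Several named genes belong to families of near-identical copies or have processed pseudogenes, among them H4C3, the SPRR1 and AKR1C genes, KRT14, KRT16 and KRT17, FTL and FTH1, SERPINB3 and HSPA8. How reads were divided among such copies is not given in the sources used here, so these values are uncertain, as are those of genes that overlap others. Some ribosomal protein genes had uneven counts too, such as RPL7A with 2253 in mod replicate 1 and 29 to 45 elsewhere. The share of ribosomal protein mRNAs is thus also uncertain, although 74 of 80 such genes were called higher in Nvs and 4 lower.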

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

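The fits without mitochondrially encoded genes, without uneven genes and with the length trend were chosen after seeing the data. Between 5159 and 6392 genes were called when each library was left out in turn, and 6617 by DESeq2's Wald test, 6491 by limma-voom, 6331 with DESeq2's size factors, 6332 without mitochondrial genes and 6578 without uneven genes; 6292 of the calls were kept with the same sign by DESeq2. No pairing is stated for the shared replicate numbers. Deviations of same-numbered libraries from their group means had correlations of -0.0178, -0.0077 and -0.023. These values show no strong shared effect of the number, but cannot settle whether the libraries were paired. With the replicate number as a block, 5949 genes were called, 3114 higher and 2835 lower, and of the 16 lists 15 were called, without the basal keratinocyte list. A threshold of 2-fold left 1257 genes, 814 higher and 443 lower, by its construction.

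Scaling decided the balance of rises and falls. By library total 10527 genes were called, 589 higher and 9938 lower. Log2(FPKM + 1) gave 577 and 8827, log2(FPKM + 0.1) 574 and 8794, and log2(FPKM + 1) without a filter 10450 genes, 556 and 9894. The shift of the median gene by -0.77 accounts for these turns. Mitochondrial counts are part of the library total, at 30.5% in mod and 52.6% in Nvs, so a part of this shift comes from their larger share. A negative value by library total is therefore not by itself evidence that a gene fell relative to other nuclear genes. By library total and log2(FPKM + 1), the log2 fold changes turned to -0.45 and -0.44 for COL7A1, -0.39 and -0.38 for NQO1, -0.22 and -0.22 for SOD1, -0.20 and -0.17 for SOD2, -0.31 and -0.30 for PLAU, -0.12 and -0.11 for HAS3, -0.34 and -0.30 for TGFA, -0.020 and -0.018 for BIK, -0.13 and -0.13 for KRT14, -0.22 and -0.21 for ADM, -0.087 and -0.082 for ALDH3A1, -0.22 and -0.21 for TIPARP, and -0.68 and -0.68 for MT2A. PI16, not called, turned to -0.53 by library total, and ranged from -0.098 to 0.61 when libraries were left out (-0.017 without mod replicate 1). A further 10 named genes kept their sign but lost their call by library total, and 3 that were not called gained a call. The rises of OASL, NFKB2, PRDX5 and BTG2 shrank to 0.05, 0.04, 0.08 and 0.08 by that scaling.

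With an estimated correlation 0 lists were called, and the adjusted p was 0.0947 for NRF2 targets, 0.346 for antioxidant enzymes, 0.202 for collagen chains and 0.0902 for collagen processing. By library total NRF2 targets had 0.155 and antioxidant enzymes 0.185, and the calls of elastic fibre and hyaluronan (0.155), interferon response (0.226) and aryl hydrocarbon receptor targets (0.163) also ended, while 3 lists were gained: nucleotide excision repair (0.0121), cholesterol biosynthesis (0.0109) and heat shock proteins (0.0450). Of the gained lists, nucleotide excision repair and heat shock proteins had medians of -0.77 and -0.76 by library total, near the -0.77 of the median gene. Collagen chains had 0.0762 with the length trend removed. By fry, which does not compare a list with other genes, 23 lists were called. Of those not called by camera, matrix proteases had 0.00214, protease inhibitors 0.00544, TGF-beta signalling 0.00120, apoptosis regulators 0.00214, senescence 0.00120, cholesterol biosynthesis 0.00273 and metallothioneins 0.0272. Matrix proteases had 0.559 in the falling direction with the length trend removed; the cause was not tested. With the trend removed 14 lists were called, 2 of which the same statistic did not call with the trend in place: the unfolded protein response (0.0111, from 0.149) and cholesterol biosynthesis (0.0369, from 0.0651). Small changes were often missed in the simulation, which found 8% of the smallest; depth was not varied there, so its part was not measured.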

Other observations

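The KEGG sets and the tests of mitochondrial share, transcript length, uneven genes and regrouped libraries were chosen or written after the results were seen; the tests of depth and of single libraries were written before theirs.

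Most genes of the KEGG ribosome set were higher in Nvs relative to the typical gene. Of 313 KEGG sets in the deposited annotation with at least 15 tested members, mitochondrially encoded genes left out, camera called 52, 14 up and 38 down, 0 of them with an estimated correlation and 25 after removal of the length trend. The ribosome set had 108 of 126 genes rising (median log2 fold change 1.01, and 0.25 by library total), and nuclear oxidative phosphorylation genes 65 of 104 (median 0.38, but -0.38 by library total), and RNA polymerase genes 18 of 32 (median 0.41, but -0.35 by library total). ECM-receptor interaction had 29 of 52 genes falling (median -0.49), other types of O-glycan biosynthesis 23 of 32, and the lysosome set 56 of 120 (median -0.30). Genes chosen after their values were seen include RPL8 (1489 ± 55.1 to 3235 ± 285 CPM) and LUC7L3, a splicing factor (346 ± 3.54 to 1467 ± 114 CPM), SREK1, UPF2 and NEAT1, a nuclear non-coding RNA (1990 ± 94.1 to 4581 ± 381 CPM). Of 39 replication-dependent histone genes 17 rose and 0 fell (median 1.06, and 0.30 by library total), while the cell cycle list fell.

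The mitochondrial share was higher in Nvs. That share was taken from the counts before any scaling, so crowding of the scaling by mitochondrial reads cannot produce it. The test written for crowding therefore decides nothing about the share. Without the mitochondrial genes 98.7% of the 6301 other called genes kept their call and sign. The log2 fold changes of shared genes moved by a median of only 0.01. The TMM-scaled calls thus depended little on the mitochondrial genes. The same refit was not made with scaling by library total. Ribosomal RNA alone is argued against by the mitochondrial mRNAs, whose share of counts differed by 11.2 percentage points. Carry-over of RNA without poly(A) tails cannot be told apart from a change in the cells, because only 2 such RNAs could be tested and their median was -0.22, with RN7SL1 at 0.59 and RMRP at -1.04, while of the histone genes, whose mRNAs mostly lack tails, 17 of 39 were called higher and 0 lower. A biological difference between the groups stays open as untested.

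Long genes were lower in Nvs. Across 12340 protein-coding genes, which are not independent, Spearman's rho of log2 fold change with genomic span was -0.403; 46.3% of 2531 genes under 10 kb rose and 7.98% fell, against 7.00% and 40.5% of 2201 genes of at least 100 kb. Transcript length alone is argued against, since rho with span given transcript length was -0.262 (95% bootstrap interval over genes -0.279 to -0.246), and so is low depth, with -0.484 among the 5586 genes of a mean CPM of at least 20. The 3 Nvs libraries, each against the mod mean, had -0.356, -0.363 and -0.396. These values argue against 1 outlying Nvs library as the source of the trend. Against the other mod libraries, mod replicate 1 had -0.135 and mod replicate 3 had 0.118, both beyond the bound of 0.1 set for no trend. A part played by single mod libraries, which enter the mod mean, therefore cannot be told apart here. A difference between the groups in transcription of long genes is a hypothesis that was not tested.

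Some genes had counts that differed widely among replicates or lay near 0. RPS18 had 10314 counts in mod replicate 1 and 3 to 12 elsewhere, and LDHA and TUBB, abundant in most cells, had at most 38 in any library. Reads shared with a second copy of the locus may be involved: in the major histocompatibility region (28 to 34 Mb of chromosome 6, also carried as alternate sequences by GRCh38) 66 protein-coding genes, 65.3%, had a total under 60 or uneven replicates, against 129 of 647, 19.9%, on the rest of the chromosome (Fisher's exact p = 2.13e-19). Of the 66, 59 only had a low total, which genes not expressed in these cells also have; among genes with a total of at least 60, 7 of 42 in the region and 5 of 523 elsewhere were uneven (Fisher's exact p = 4.58e-06). Against 1 aberrant library, no library held the highest CPM of more than 22.2% of the 162 uneven genes.

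Regrouping the 6 libraries gives 10 splits, too few for a share under 0.05. The real split called 6328 genes and the highest other 1; as many were called in 1 split, the real one. It called 16 lists and the highest other 6, and again 1 split called as many.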
